A study of Mus musculus with 157 samples.

How the data were processed

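The series holds 157 mouse samples of haematopoietic cell types. The wild-type atlas has 32 input RNA libraries and 32 libraries of RNA precipitated with an antibody against N6-methyladenosine (m6A), 2 of each for 16 cell types. The Mettl3 set has 14 input and 14 precipitated (IP) libraries of the knockout and as many of the wild type, 2 per genotype in each of 7 cell types. The Igf2bp2 set has 2 knockout and 2 wild-type libraries of LT.HSC, the long-term haematopoietic stem cell. SLAM-seq, which marks RNA made during a pulse of 4-thiouridine by T-to-C changes in the reads, was given for 12 libraries of 6 cell types after 3 h of labelling, and for 21 samples of LT.HSC and MkP, the megakaryocyte progenitor, at 7 chase times after 24 h of labelling. Cell type names are those of the labels. The labels do not say which replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

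The submitters' processing notes name fastp, Trimmomatic, kallisto and the mouse assembly GRCm38, per the labels. Their versions, their roles for each file and the annotation are not given in the sources used here. The authors deposited whole-number counts per gene symbol for the atlas IP and Igf2bp2 libraries. For the Mettl3 IP libraries the authors deposited estimated counts with fractions, which were rounded to whole numbers before testing. The deposited input values of the atlas and of the Mettl3 set are a normalised signal, counts divided by a size factor for each library. There, 100% of the values were whole multiples of a single step per library, within a tolerance of 0.1 of a read, so whole reads could be recovered. In the second GMP library of the atlas the step was too near 1 for this rule to be applied on its own. The SLAM-seq values are deposited as a fraction per gene, the T-to-C ratio, and are printed here as percent. Its denominator and any background correction are not given in the sources used here, and the depth behind the ratios is unknown. The chase ratios of LT.HSC and of MkP were both deposited under the name of averages, with no replicate values. The labels list replicate samples at each chase time for LT.HSC but only a single sample at each time for MkP. What the MkP averages were taken over is therefore unknown. The design had assumed normalised counts for the inputs, counts for the IP and Igf2bp2 tables and ratios for SLAM-seq, and the tests were kept as planned.

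Comparisons, the rule for named genes, 21 gene lists and most alternative settings were chosen before the data were examined. Inputs were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with the mean-variance trend, keeping genes with a value of at least 10 in at least 2 libraries. Each group had its own mean and all libraries of a table shared the estimate of the spread. Fold changes are on this scale and understate changes of genes near 0. The atlas expression fit alone used robust moderation. The m6A enrichment of a gene was its log2 IP value minus its log2 input value. Because IP and input tables were scaled separately, gene tests were made only on differences of this quantity between cell types or genotypes. They used a single limma fit over both tables with TMM factors within each table. The level within LT.HSC was used only to rank genes, for a gene set and for a correlation with half-life. A loss of m6A shared by all genes is removed by this scaling. The Mettl3 IP counts and the Igf2bp2 counts were tested with the quasi-likelihood test of edgeR 4.0.16 after filterByExpr and TMM scaling, with DESeq2 1.42.0 as an alternative. New RNA ratios were tested with limma on log2(percent + 0.1) for genes above 0 in at least 6 libraries. All p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

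Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The lists were the m6A writer complex, m6A erasers, m6A readers, stem cell regulators, cell cycle, oxidative phosphorylation, mitochondrial biogenesis and dynamics, interferon response, Myc and ribosome biogenesis, p53 targets, immediate early and heat shock genes, ribosomal proteins, and markers of T cells, B cells, dendritic cells, erythroid cells, monocytes, neutrophils, granulocyte monocyte progenitors, megakaryocytes and lymphoid progenitors. A list of 10 mast cell and basophil genes was added after the results were seen. Genes were named by rule: the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 50 and no overlap between the groups, without Gm and Rik models. Mettl3, Igf2bp2, Bmi1, Myc, Gata2, Mecom and Cdkn1c were named too, with members of each list. Not every gene under the rule is described. For the Mettl3 averages few genes met the overlap condition, so the 8 highest and 8 lowest without it were added after their values were seen. Further genes named in the text for MEP, for Igf2bp2 and among cell type markers were also chosen after their values were seen.

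RNA half-lives were fitted for each gene with a ratio at 4 or more of the 7 times, as a least-squares line through the natural logarithm of the ratio against time. Half-lives were kept where the slope was below 0 and R squared was at least 0.5. These values have no replicates and no test, and 95% intervals of medians and shares are across genes, which are not independent replicates.

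Library depth ranged from 8.23 to 21.5 M reads in the atlas inputs, from 10.8 to 24.6 M in the atlas IP, from 3.42 to 20.2 M in the Mettl3 inputs, from 0.819 to 22.9 M in the Mettl3 IP and from 4.68 to 20.0 M in the Igf2bp2 libraries. No pair of libraries held identical values. The tests of single genes listed here were run on simulated data with 200 genes changed by known amounts. Simulated libraries varied independently, and groups were alike except in the changed genes. Outside the new RNA test the changed genes had a mean of at least 50. Structure shared by libraries of the same replicate number, as found in the Mettl3 inputs, was not simulated. Recovery may therefore be lower, and false calls more frequent, in the real data. At a 4-fold change the tests recovered 96% of changed genes for LT.HSC expression among 16022 simulated genes and 88% for the Mettl3 average among 15103. Recovery was 18% in MEP alone among 15103 genes and 2% for differences among cell types among 15085. It was 74% for LT.HSC enrichment against the other types and 44% against MkP among 15630, 52% for the Mettl3 enrichment average among 14220 and 58% for the Mettl3 IP counts among 17170. For the Igf2bp2 comparison edgeR recovered 0% at 4-fold and 66% at 16-fold among 12826 genes, while DESeq2 recovered 16% at 4-fold among 13439 with 28 other genes called. The new RNA test recovered 4% among 13891. Simulated half-lives had a median error of 2.92% over 1000 genes. That simulation had a pure exponential decay with a value at every time, unlike the deposited ratios, so it does not measure their error.

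Gene positions are from the RefSeq annotation of GRCm38.p6, matched by symbol for 29876 of 36102 genes. Alternative settings changed the scaling, pseudocount, filter, tool, replicate block, time points and fit filter, left out each library in turn, and left out doubtful libraries. Those chosen after seeing the data were edgeR on recovered reads, leaving out the Erythroid and Monocyte libraries, leaving out 4 doubtful Mettl3 libraries, robust moderation, means per genotype and replicate number, half-lives from genes with a ratio at all 7 times, an Igf2bp2 gene set at an unadjusted p, and gene lists in MEP.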

Results

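The data covered the transcriptome and its m6A marks across mouse haematopoiesis. Input and IP libraries were made in 16 wild-type cell types, from LT.HSC and progenitors to B_cell, CD4, CD8, DC, Erythroid, Monocyte and Neutrophil populations, with 2 libraries per type and kind. Mettl3 encodes the catalytic subunit of the m6A methyltransferase, and its knockout was profiled in LT.HSC, ST.HSC, MPP, CMP, GMP, MEP and MkP with 2 libraries per genotype, type and kind. Igf2bp2 encodes an m6A reader, and its knockout was profiled in LT.HSC with 2 libraries per genotype. SLAM-seq gave new RNA in 6 types and RNA decay in LT.HSC and MkP. Median depth was 14.5 M reads in atlas inputs, 16.9 M in atlas IP, 10.4 M in Mettl3 inputs, 13.8 M in Mettl3 IP and 5.71 M in the Igf2bp2 libraries. Replicates correlated with a median r across genes of 0.961 in atlas inputs, 0.939 in atlas IP, 0.912 in Mettl3 inputs, 0.730 in Mettl3 IP and 0.772 in the Igf2bp2 libraries. The atlas IP libraries of LT.HSC correlated at 0.742, the lowest of the 16 types in the atlas IP. The atlas enrichment results for LT.HSC rest on this pair. Of the Mettl3 libraries, wild-type IP LT.HSC 1 had 94.2% of its counts in 10 genes and wild-type IP ST.HSC 1 had 75.8%. Knockout IP MEP 1 held 0.819 M counts, and the wild-type LT.HSC inputs correlated at 0.586.

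LT.HSC libraries were first compared with the other 15 cell types, to describe what sets the stem cell apart. The stem cell regulators were far higher in LT.HSC. Mecom, a transcription factor needed for stem cell maintenance, had a normalised read count of 1490 ± 94.1 (SD, n = 2) against 61.7 ± 132 in the 30 other libraries, a log2 fold change of 6.62 (SE 0.56, limma adjusted p = 3.18e-09). Mmrn1, which encodes the platelet and endothelial protein multimerin, was higher by 7.48 (SE 0.67, adjusted p = 7.62e-09), at 2382 ± 542 against 72.9 ± 164. At the other end, the leukocyte adhesion gene Jaml (0.898 ± 0.687 against 1489, adjusted p = 3.68e-14) was nearly unread in LT.HSC, and Slc2a6 was listed at 0 in both libraries.

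Other genes of the top group were Grb10 (6.39), an adaptor of growth factor receptors, the lectin gene Clec1a (6.37), Trim47 (6.33) and the caveola genes Cavin3 (5.92) and Cavin1 (5.86). The immunoglobulin M heavy chain gene Ighm was lower by −6.92 (SE 0.58, adjusted p = 5.86e-09), and Mpeg1, the perforin of macrophages, Cox6a2, Rab7b and Alox5 stood below 1 in LT.HSC. In total 3915 of 17165 genes were higher and 3011 lower, and 15925 differed among the 16 types by the F test. Leaving out LT.HSC 2 gave 2292 higher and 1685 lower genes, and leaving out LT.HSC 1 gave 2336 higher. In the GRCm38.p6 annotation Mmrn1 lies on chromosome 6 from 60944317 to 60989378 and Mecom on chromosome 3 from 29951296 to 30509759.

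**Figure D1:**
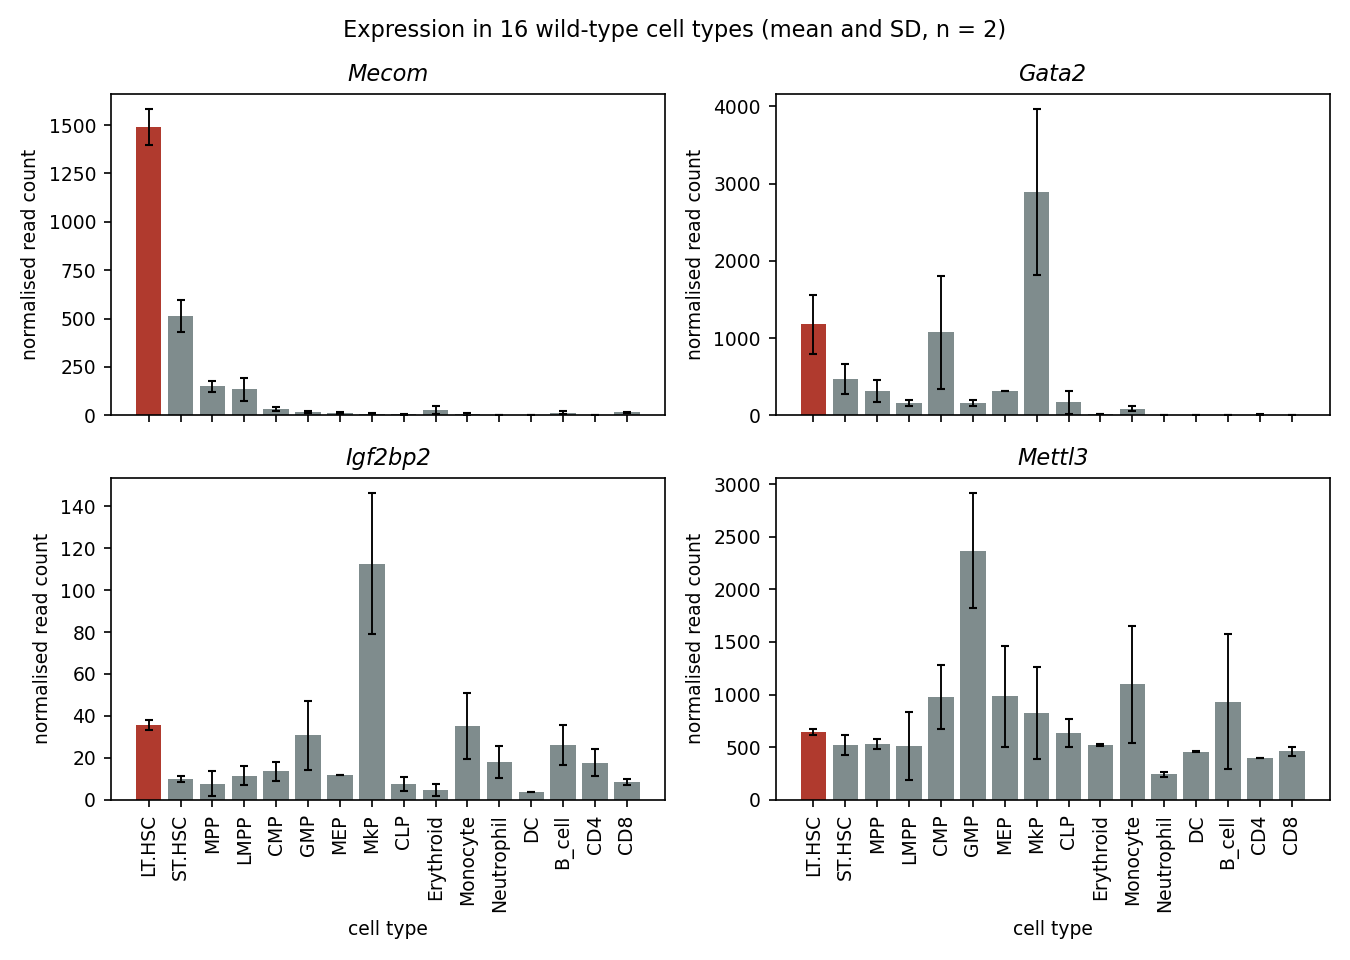
Normalised read counts of Mecom, Gata2, Igf2bp2 and Mettl3 in 16 wild-type cell types; bars are means of 2 libraries, error bars are SD and LT.HSC is red. Mecom peaked in LT.HSC at 1490, Igf2bp2 in MkP at 113 and Mettl3 in GMP at 2369.

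Of the 30 stem cell regulators, 27 rose and none fell in LT.HSC (28 adjusted over the list alone, camera adjusted p = 5.50e-20), among them Procr, the protein C receptor (6.25), and the growth suppressor Ndn (6.20). Gata2 (4.10, adjusted p = 7.28e-07) and the cell cycle inhibitor Cdkn1c (5.45, adjusted p = 6.28e-07) were part of this list, while Bmi1 was not past the threshold (0.26, adjusted p = 0.692). The mean of Gata2 was highest in MkP, at 2894.5 against 1178 in LT.HSC. Of 12 megakaryocyte markers 9 rose, including the platelet glycoprotein gene Gp9 (3.52) and Vwf, which encodes von Willebrand factor (3.42), and 1 fell (9 and 1 adjusted over the list alone). Their camera adjusted p was 0.00149, and the adjusted p = 0.159 with an estimated correlation. Of 30 cell cycle genes 19 fell and 2 rose (20 and 2 adjusted over the list alone, camera adjusted p = 2.81e-07), with the cyclin gene Ccna2 at −3.06, the ribonucleotide reductase gene Rrm2 at −2.90 and Birc5 at −2.44. Oxidative phosphorylation genes were lower in 42 of 53 cases (50 adjusted over the list alone), led by cytochrome c, Cycs (−2.60), and Cox5a (−2.41). The camera adjusted p of that list was 1.04e-13, and the adjusted p = 0.204 with an estimated correlation.

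Markers of mature and committed cells were mostly lower. All 8 monocyte markers fell (8 adjusted over the list alone, camera adjusted p = 8.10e-10), led by Ly6c2 (−6.89) and the clotting factor gene F13a1 (−4.51). The T cell list fell in 9 of 11 genes (9 adjusted over the list alone, camera adjusted p = 5.60e-06), the B cell list in 7 of 9 (8 adjusted over the list alone, camera adjusted p = 8.21e-06), and the lymphoid progenitor list in 5 of 8 with 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.00991), with Dntt at −3.43 and Il7r at −3.27. All 9 neutrophil markers fell (9 adjusted over the list alone, camera adjusted p = 6.08e-07, and adjusted p = 0.0696 with an estimated correlation). The granulocyte monocyte progenitor list fell in 6 of 7 genes (6 adjusted over the list alone, camera adjusted p = 1.03e-05, and adjusted p = 0.108 with an estimated correlation), led by the granule protease genes Ctsg (−5.05) and Elane (−4.56) and by Mpo (−4.77). Dendritic cell markers fell in 8 of 10 genes (8 adjusted over the list alone, camera adjusted p = 1.92e-04, and adjusted p = 0.159 with an estimated correlation), with Irf8 at −5.83. Erythroid markers went both ways, with the erythropoietin receptor gene Epor (2.86) and Car2 (2.28) as the 2 that rose, while 5 fell (camera adjusted p = 0.166).

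Of the m6A machinery, Mettl3 was not past the threshold in LT.HSC (0.03, SE 0.34, adjusted p = 0.952). Of 9 writer genes Virma alone rose (0.80, adjusted p = 0.0282, none adjusted over the list alone, camera adjusted p = 0.835). Of the 2 erasers Fto rose (0.93, adjusted p = 0.00821, camera adjusted p = 0.833). Of 12 readers 2 rose and 4 fell (camera adjusted p = 0.306). Igf2bp2 was higher by 1.32 (SE 0.47, adjusted p = 0.0276), at 35.6 ± 2.50 against a mean of 21.2, with its highest level in MkP (113 ± 33.6), while Hnrnpa2b1 (−1.96) and Elavl1 (−1.32) fell. Immediate early and heat shock genes fell in 3 of 17 cases, led by Fos at −3.84 (camera adjusted p = 0.0139, and adjusted p = 0.346 with an estimated correlation). Lists with no call were ribosomal proteins (6 of 30 fell, 1 adjusted over the list alone, camera adjusted p = 0.0582, Rpl10 at −1.07), interferon response (6 higher and 2 lower of 30, camera adjusted p = 0.835, Ifi44 at 2.03 and Ifi27l2a at −3.91), Myc and ribosome biogenesis (4 higher and 3 lower of 25, camera adjusted p = 0.746, Polr1b at 2.27) and p53 targets (1 higher and 4 lower of 14, camera adjusted p = 0.147, Plk2 at 3.90 and Btg2 at −3.74). Mitochondrial biogenesis and dynamics genes had 5 higher and 6 lower of 17 (camera adjusted p = 0.833), with a positive median of 0.09 and a test in the lower direction. Myc, which drives growth and ribosome synthesis, was higher than the mean of the other types by 1.20 (SE 0.30, limma adjusted p = 0.00288). Its mean of 2907 in LT.HSC lay below those of MkP (8103.5), MEP (5364), ST.HSC (5272), GMP (5093), CMP (4692) and MPP (4045). It lay above those of the remaining types.

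The next comparison asked which transcripts differed in m6A enrichment, the IP signal relative to input, in LT.HSC. Against the mean of the other 15 types, enrichment was lower for Gfi1, a transcriptional repressor of stem and myeloid cells, by −7.04 (SE 0.69, limma adjusted p = 1.16e-08, 4 LT.HSC libraries against 60), for Vps51, a subunit of an endosome tethering complex, by −7.72 (SE 0.59, adjusted p = 8.69e-12), and for the chromatin reader gene Mllt1 by −5.65 (SE 0.72, adjusted p = 2.35e-06). It was higher for Neu1, the lysosomal sialidase, by 3.70 (SE 0.47, adjusted p = 1.79e-06), and for Nostrin by 4.18 (SE 1.06, adjusted p = 0.00908). Hist1h2ab (4.82) and Ly6c2 (3.34) were also higher, but both have close copies in the genome whose reads may have been split. Against MkP, the type paired with LT.HSC in the decay experiment, Igf2bp2 was itself more enriched in LT.HSC by 4.18 (SE 1.05, adjusted p = 0.00998), and Gfi1 (−8.52, adjusted p = 3.66e-07), Vps51 (−7.77), Zfp335 (−7.48) and Tarbp1 (−7.39) less. Further genes less enriched against the other types were Slc46a3 (−5.93), Enc1 (−5.79), Dnaaf3 (−5.73) and Fancg (−5.69). Against MkP, Add2 (7.22), Tigit (6.00) and Rnd1 (5.66) were more enriched. Of the genes past the threshold that were followed across settings, 11 of 16 kept the call in every setting against the 15 types. Against MkP 5 of 17 did, and 12 lost it in some setting.

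Enrichment of Mettl3 (1.12, adjusted p = 0.153), Igf2bp2 (2.08, adjusted p = 0.0761), Myc (−1.18, adjusted p = 0.103) and Bmi1 (−0.60, adjusted p = 0.734) was not past the threshold against the 15 types. In total 298 of 16639 genes were more and 1357 less enriched in LT.HSC than in the other types, and 263 more and 1157 less than in MkP. These counts rested on single libraries. Against the 15 types they were 137 and 681 without input LT.HSC 1, 117 and 368 without input LT.HSC 2, 1104 and 2464 without IP LT.HSC 2, and 755 lower without IP LT.HSC 1. Against MkP they were 142 and 615 without input MkP 1, 763 and 1963 without IP LT.HSC 2, 147 and 754 without input LT.HSC 1, and 391, 771 and 729 lower without input LT.HSC 2, input MkP 2 and IP MkP 1. Differences of genes near 0 in either kind of library depend on the pseudocount, and with 10 instead of 1 the counts of more enriched genes were 695 and 573. In the wild-type libraries of the Mettl3 set, 705 of 1325 genes called against MkP (53.2%) had the same sign, and the correlation of the differences across 13213 genes was 0.047. Without doubtful libraries these values were 48.2% and 0.018.

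In the Mettl3 set the targeted gene was checked first. Mettl3 had a normalised read count of 274 to 931 in the 14 input libraries labelled knockout. In those labelled wild type it stood at 127 to 656, except 5371 in LT.HSC 1. Averaged over the 7 types it was not past the threshold (log2 fold change 0.06, SE 0.26, adjusted p = 0.90). Which part of the gene was deleted is not given in the sources used here, so reads of the gene do not check the labels, and directions below rest on them.

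Averaged over the 7 types, RNA of Gdf15, Dlk1 and Tnfaip8l1 rose in the libraries labelled Mettl3 knockout, and RNA of Mmrn1 and Igf2bp2 fell. The 14 libraries of a genotype are 2 numbered libraries in each of 7 types. Those with the same number deviated together in part, so the adjusted p-values treat related libraries as independent. Of 19 genes past the threshold that were followed across settings, 0 kept the call in every setting. Gdf15, a stress cytokine and p53 target, stood at 144 ± 112 (SD, n = 14) against 19.5 ± 22.9, a log2 fold change of 3.26 (SE 0.50, limma adjusted p = 2.63e-04). Dlk1, a non-canonical Notch ligand, was higher by 4.33 (SE 0.54, adjusted p = 3.34e-05), and Tnfaip8l1 rose from 50.4 ± 36.0 to 547 ± 407 (3.47, SE 0.40, adjusted p = 1.33e-05). Mmrn1 fell from 246 ± 299 to 17.1 ± 19 (−3.17, SE 0.55, adjusted p = 7.25e-04), and Igf2bp2 fell from 66.1 ± 75.1 to 16.9 ± 11 (−1.44, SE 0.43, adjusted p = 0.0342). With every knockout library apart from every wild-type library, Wdr53 rose (420 ± 116 against 206 ± 53.6, 1.05, adjusted p = 8.44e-04) and Gon7, a subunit of the KEOPS complex that modifies transfer RNA, fell (119 ± 41.4 against 263 ± 150, −1.11, adjusted p = 0.00385).

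Other large increases were the collagen chaperone genes Fkbp10 (4.32) and Serpinh1 (3.21), Grrp1 (3.62), Lrg1 (3.45) and Tmem215 (3.35). Decreases included Cpxm1 (−3.28), the pseudokinase gene Trib2 (−2.93), Zfp783 (−2.60), the proteasome subunit gene Psma8 (−2.58), Crispld1 (−2.56), Gdf3 (−2.46) and Lipo3 (−2.43). Bmi1 (−0.71, adjusted p = 0.385), Myc (−0.11, adjusted p = 0.722), Gata2 (0.57, adjusted p = 0.167), Mecom (−0.04, adjusted p = 0.961) and Cdkn1c (1.12, adjusted p = 0.217) were not past the threshold. In total 1088 of 15030 genes rose and 434 fell. A fit on 1 mean per genotype and replicate number, 2 against 2, called 1 gene higher and 0 lower. The count of lower genes lay between 221 and 286 when the second replicate of knockout CMP, GMP, LT.HSC, MEP, MPP or MkP or of wild-type CMP, GMP, MEP, MPP or MkP was left out, and was 761 without wild-type LT.HSC 2 and 1247 without knockout ST.HSC 2.

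Of 15 p53 targets 7 rose (9 adjusted over the list alone, camera adjusted p = 2.04e-04, and adjusted p = 0.240 with an estimated correlation), including the apoptosis gene Perp (2.34), Eda2r (2.27) and Phlda3 (1.98). Stem cell regulators rose in 9 of 30 cases and fell in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00349, and adjusted p = 0.592 with an estimated correlation), with Hoxb5 (2.65), the junction gene Esam (2.19), Mycn (1.83) and Ly6a (1.64) higher. Neutrophil markers rose in 4 of 9 cases (7 adjusted over the list alone, camera adjusted p = 2.04e-04, and adjusted p = 0.592 with an estimated correlation), the granule genes Ltf (3.14), Lcn2 (2.70) and Ngp (2.33) and the calcium-binding gene S100a9 (2.56). Granulocyte monocyte progenitor markers rose in 2 of 7 cases, Ms4a3 (2.18) and Calr (0.90) (4 adjusted over the list alone, camera adjusted p = 0.00349, and adjusted p = 0.765 with an estimated correlation). Of 10 mast cell and basophil genes, listed after the results were seen, 4 rose: the granzyme gene Gzmb (4.39), Cd200r3 (3.07), the IgE receptor gene Fcer1a (3.01) and Cpa3 (1.07).

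The other lists were not called. Interferon response genes rose in 7 of 30 cases (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.480), with Zbp1 (1.52), Oasl1 (1.26) and Rtp4 (1.13), and their median of −0.17 was opposite in sign to the test. Monocyte markers rose in 2 of 8 cases (Ms4a6c at 1.06 and Lyz2 at 1.01, camera adjusted p = 0.170), and in the dendritic cell list Cd74 rose (1.66, camera adjusted p = 0.170). In the megakaryocyte list Itgb3 (1.70) and Itga2b (1.06) rose and Gp1bb fell (−2.41, camera adjusted p = 0.480). In the cell cycle list E2f1 (0.79) and Ccnd1 (0.71) rose and Mcm4 fell (−0.71, camera adjusted p = 0.480). Single genes passed among the readers besides Igf2bp2 (Ythdf2, 0.72), B cell markers (Cd79b, 0.75), Myc and ribosome biogenesis (Nop2, 1.00) and lymphoid progenitor markers (Flt3, −1.55). Of 9 writer genes 1 was lower when adjusted over the list alone, Wtap (−1.18, adjusted p = 0.0518 over all genes). None of the measured writers, erasers, oxidative phosphorylation, mitochondrial biogenesis, ribosomal protein, T cell, erythroid or immediate early genes passed over all genes.

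Within single types, 321 genes rose and 1 fell in MEP. P2rx1, an ATP-gated channel of platelets, stood at 133 ± 41.8 (SD, n = 2) against 1.39 ± 1.96 (limma adjusted p = 3.87e-05), Itgb3, the platelet integrin beta chain, at 116 ± 90.8 against 0.527 ± 0.745 (adjusted p = 1.53e-04), and Mylk, the myosin light chain kinase, at 174 ± 15.7 against 2.77 ± 3.92 (adjusted p = 1.53e-04). The junction gene F11r rose by 5.26 (SE 0.66, adjusted p = 1.53e-04), from 17.5 ± 5.11 to 696 ± 95.3. Laptm4b, Serpina3g, Gchfr and Fcer1a were the other 4 of the top group. Stem cell regulators rose in 7 of 30 cases (12 adjusted over the list alone, camera adjusted p = 4.42e-12, and adjusted p = 0.0131 with an estimated correlation), including Meis1 (1172 ± 91.0 against 91.3 ± 15.8) and Esam (829 ± 242 against 39.2 ± 3.30). Megakaryocyte markers rose in 3 of 12 cases (7 adjusted over the list alone, camera adjusted p = 1.34e-10, and adjusted p = 0.0164 with an estimated correlation), among them Itgb3 and Itga2b (1777 ± 449 against 156 ± 104). Monocyte markers and p53 targets were called higher, and cell cycle, oxidative phosphorylation, mitochondrial biogenesis and Myc lists lower, at the preset correlation alone (camera adjusted p = 0.0301 for monocyte markers, and adjusted p = 0.475 with an estimated correlation). These list tests in MEP were added after the counts were seen. Without knockout MEP 1, knockout MEP 2, wild-type MEP 1 or wild-type MEP 2 the test called 147, 118, 213 or 141 genes, with a pseudocount of 10 it called 195, and edgeR on recovered reads called 165.

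In LT.HSC 60 genes rose and 21 fell. Tnfaip8l1 stood at 1055 ± 684 against 12.2 ± 9.48 (adjusted p = 0.0175), Gzmb at 104 ± 58.3 against 0.344 ± 0.486 (adjusted p = 0.0175) and Gdf15 at 263 ± 160 against 3.10 ± 3.41 (adjusted p = 0.0372). B3gnt9, Cyb561, the TWEAK receptor gene Tnfrsf12a, Hpn and Adat3 rose too. Apbb1, whose protein binds the amyloid precursor protein (8.03 ± 2.81 against 697 ± 731) and Aplp2, a relative of that precursor (179 ± 121 against 996 ± 135), fell, as did Vnn1, Itsn1 and Zfp386. No gene list was called there (smallest camera adjusted p = 0.289). The LT.HSC count depended on each of its libraries: it was 210 without knockout 1, 0 without knockout 2, 3 without wild type 1 and 1611 without wild type 2, it was 172, 174, 24 and 24 without knockout ST.HSC 1, knockout ST.HSC 2, wild-type CMP 1 and wild-type CMP 2, and edgeR on recovered reads called 0.

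In MkP 15 genes rose and 2 fell, among them Gzmb (159 ± 109 against 0.202 ± 0.286, adjusted p = 0.00835), Csf2rb, a receptor chain for granulocyte cytokines (890 ± 680 against 37.5 ± 39.4, adjusted p = 0.0107), Rgs3 (5.46), Rtkn (5.15), Sytl1 (5.09) and Eps8 (5.04), with Sh3d21 and Arhgef10l. Gdf3 (−4.47) and Adamtsl5 (−4.38) fell. The knockout MkP libraries were unlike each other in granule RNA, with Mpo at 1407 and 37011. The MkP count was 4, 1, 351 and 1 without knockout 1, knockout 2, wild type 1 and wild type 2, and edgeR on recovered reads called 0. In ST.HSC 2 genes rose, Tmem215 (453 ± 265 against 0.403 ± 0.569) and the P-selectin gene Selp (5858 ± 290 against 395 ± 277, 4.09). Without knockout ST.HSC 2 that count was 1607, without wild type 2 it was 4, and it was 0 without knockout 1 or wild type 1. On recovered reads edgeR called 1 gene in ST.HSC, 0 in MPP and 0 in CMP. In MPP the immunoglobulin kappa segments Igkv12-44 and Igkv1-135 rose, members of a family with near-identical copies. That count was 0 without any of the 4 MPP libraries and 6 without knockout ST.HSC 1 or knockout ST.HSC 2. In CMP 1 gene rose, the gene model A430089I19Rik, and none without knockout 1, wild type 1 or wild type 2. In GMP limma and edgeR on recovered reads both called 0 genes, with 229 at an unadjusted p under 0.05 by limma. A difference between types was tested by the interaction, which called 2 genes, P2rx1 and A430089I19Rik (both adjusted p = 0.0157, 629 at an unadjusted p under 0.05). It called 78 genes without knockout ST.HSC 2, 68 without wild-type LT.HSC 2, 37 without wild-type MkP 1, 5 without knockout LT.HSC 1, 4 without wild-type LT.HSC 1, 1 without knockout MEP 1, and 0 without knockout MEP 2 or knockout MkP 1.

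**Figure D2:**
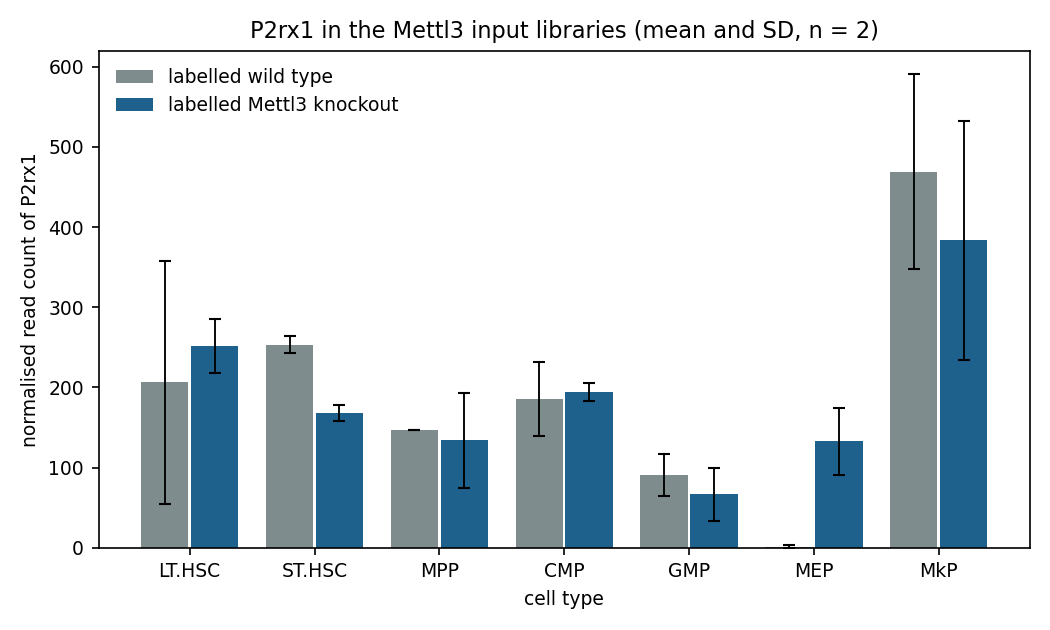
Normalised read counts of P2rx1 in libraries labelled Mettl3 knockout and wild type in 7 cell types; bars are means of 2 libraries and error bars are SD. In MEP the knockout mean was 133 and the wild-type mean 1.39, and in ST.HSC the means were 168 and 253.

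The m6A enrichment of single transcripts was then compared between Mettl3 genotypes. No transcript lost or gained enrichment past the threshold on average over the 7 types. Enrichment of Myc differed by −0.38 (SE 0.36, limma adjusted p = 0.993), of Bmi1 by −0.15 (SE 0.78, adjusted p = 1.00), of Gata2 by 0.08 (SE 0.45, adjusted p = 1.00) and of Mecom by 0.65 (SE 0.82, adjusted p = 0.993), and limma called 0 of 14466 genes, with 617 at an unadjusted p under 0.05. It called 3 higher and 4 lower genes without wild-type IP ST.HSC 2, and 10 lower without wild-type IP LT.HSC 2. Because IP tables were scaled to their own totals, a loss common to all transcripts would not appear here. In MkP 4 transcripts gained enrichment: Dipk1a (9.29, adjusted p = 3.42e-04), the apoptotic initiator gene Casp9 (9.28, adjusted p = 0.0385), Vgll4 (7.48, adjusted p = 0.0252) and Dtwd1 (5.18, adjusted p = 0.0385), and in MEP 1 did. Limma called 0 in CMP, GMP, LT.HSC, MPP and ST.HSC, with 86, 692, 1182, 59 and 1009 at an unadjusted p under 0.05. Single libraries again changed the counts, to 2612 in GMP without knockout IP GMP 2 and 56 in CMP without knockout IP CMP 2. In ST.HSC they were 783 without wild-type IP ST.HSC 2, 7 without knockout input ST.HSC 2, 3 without either knockout IP GMP library and 2 without knockout IP ST.HSC 2. In LT.HSC they were 201 without wild-type IP LT.HSC 2, 160 without knockout IP LT.HSC 2, 6 without wild-type IP LT.HSC 1, 3 without wild-type input LT.HSC 2, 2 without any of knockout IP GMP 1 and the wild-type IP libraries of MkP and ST.HSC, and 1 without knockout IP GMP 2. In MEP the call was lost without any of 6 of its 8 libraries, those other than wild-type input MEP 2 and knockout IP MEP 1. In MkP the count was 620 without wild-type IP MkP 2, 41 and 40 without knockout IP GMP 2 and 1, 16 and 14 without wild-type IP LT.HSC 1 and 2, 10 without wild-type IP MkP 1 or knockout IP MkP 2, and 1 or 2 in 30 of the other refits.

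The IP counts alone were also compared between genotypes. They carry changes of RNA level as well as of m6A, and this comparison does not separate the 2. The 14 libraries of a genotype, 2 in each of 7 types, may not be independent replicates. Of 16 genes past the threshold that were followed across settings, 4 kept the call in every setting. Precipitated RNA of Dlk1 (4.98, SE 1.03, edgeR adjusted p = 0.0152), Lrg1 (5.20, SE 1.21, adjusted p = 0.0380), Gdf15 (4.37, SE 0.88, adjusted p = 0.0136) and Fcer1a (4.06, SE 0.77, adjusted p = 0.00833) was higher in the knockout, with n = 14 per genotype. Gp1bb, a platelet glycoprotein gene (−3.73, SE 0.77, adjusted p = 0.0152), and Gdf3 (−3.45, SE 0.60, adjusted p = 0.00384) were lower. In the input libraries Dlk1, Lrg1, Gdf15 and Fcer1a were higher too, and Gp1bb and Gdf3 lower. Enrichment, the IP value relative to input, was called for 0 of 14466 genes on average. Aif1l (5.60), Spats2 (5.32), Fam20c (4.61) and Plbd1 (4.31) rose, and Klk8 (−3.09), Tbrg4 (−2.78), Pdcd4 (−2.75), Omd (−2.71), Rbm25 (−2.70) and Zfp322a (−2.67, adjusted p = 0.0492) fell. In total 77 of 17463 genes rose and 27 fell by edgeR, and 689 and 203 by DESeq2. In refits with libraries left out the low-count filter was set anew, and it is looser where a group has a single library. Leaving out the filter alone also raised both counts. Its part in the changes below was not separated from that of the libraries. Any left-out library raised the counts, to between 82 (knockout ST.HSC 1) and 270 (wild-type MkP 2) higher genes and between 34 (knockout ST.HSC 1) and 154 (knockout ST.HSC 2) lower genes. Without 3 doubtful IP libraries Zfp322a turned to 0.34 and 196 genes rose.

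In the Igf2bp2 set the reads of Igf2bp2 did not separate the labels. The libraries labelled knockout held 61 and 81 counts (13 and 12.5 CPM), and those labelled wild type 142 and 263 (7.11 and 53.5 CPM), a log2 fold change of −0.87 (edgeR adjusted p = 0.971). Which part of the gene was deleted is not given in the sources used here. Bmi1, a polycomb gene of stem cell self-renewal on chromosome 2 from 18677018 to 18686629, had 1 count in each library labelled knockout and 235 and 135 in those labelled wild type. Its adjusted p was 0.618 by edgeR and 0.00934 by DESeq2, where its log2 fold change was −6.38 (SE 1.57). Several granule genes and a B cell gene had higher levels in the libraries labelled knockout, without passing the edgeR threshold. Elane, neutrophil elastase, stood at 2520 and 155 CPM against 52.9 and 19.9, Retnlg at 165 and 121 against 28.2 and 8.94, and the B cell receptor gene Cd79a had 182 and 130 counts against 2 and 0. The granule protease gene Ctsg was high in knockout 1 alone, at 266 and 3.08 CPM against 4.95 and 2.64.

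**Figure D3:**
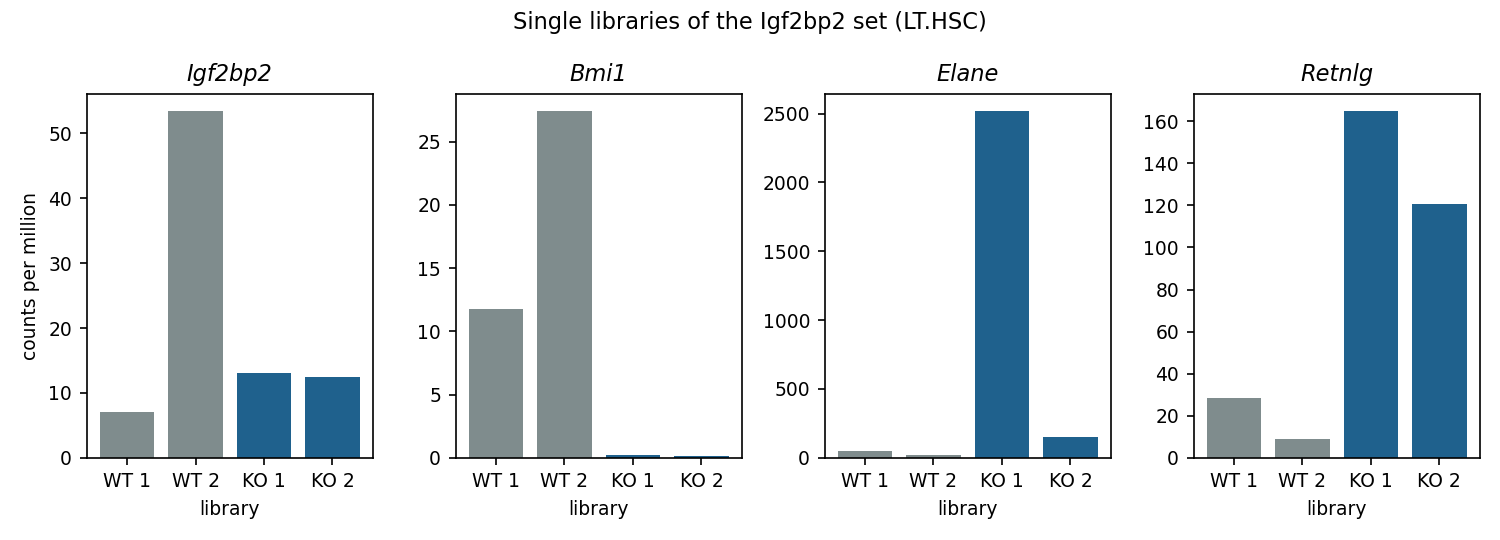
CPM of Igf2bp2, Bmi1, Elane and Retnlg in each of the 4 LT.HSC libraries labelled Igf2bp2 knockout or wild type. Igf2bp2 in the libraries labelled knockout lay at 13 and 12.5 CPM, between the wild-type values of 7.11 and 53.5.

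No gene passed by edgeR (0 of 12221, 777 at an unadjusted p under 0.05), and DESeq2 called 86 higher and 66 lower. No list member passed over all genes. Neutrophil markers had a median of 2.93 (5 of 9 higher adjusted over the list alone, camera adjusted p = 3.89e-09, and adjusted p = 0.642 with an estimated correlation) and granulocyte monocyte progenitor markers one of 2.89 (6 of 7 adjusted over the list alone, camera adjusted p = 1.05e-05, and adjusted p = 0.642 with an estimated correlation). Oxidative phosphorylation genes had a median of 1.02 over 53 genes (camera adjusted p = 2.17e-16, and adjusted p = 0.642 with an estimated correlation), with Atp5e at 1.76 and Ndufs6 at 1.70. Ribosomal proteins (camera adjusted p = 8.29e-05, and adjusted p = 0.667 with an estimated correlation), B cell markers (4.81e-04, and adjusted p = 0.642 with an estimated correlation) and monocyte markers (0.0262, and adjusted p = 0.667 with an estimated correlation) were called higher, and megakaryocyte markers lower (0.0122, and adjusted p = 0.642 with an estimated correlation). Stem cell regulators had a median of −0.46 over 29 genes (camera adjusted p = 0.0973). For T cell markers the median of −0.53 was opposite in sign to the test. Limma called no gene as less enriched in the Mettl3 knockout on average (617 in either direction at an unadjusted p under 0.05), so the planned set of METTL3-dependent transcripts was empty. The 2901 transcripts with the highest enrichment in LT.HSC were not called as a set in the Igf2bp2 comparison (camera p = 0.204, and p = 0.244 with an estimated correlation).

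New RNA after 3 h of labelling was compared among 6 types. The median T-to-C ratio over genes was highest in MPP (1.65% ± 0.0862, SD over 2 libraries) and CMP (1.41% ± 0.0280) and lower in ST.HSC (0.842% ± 0.0572), MEP (0.820% ± 0.432), GMP (0.704% ± 0.559) and LT.HSC (0.668% ± 0.251), with the GMP libraries at 1.10% and 0.309%. In LT.HSC the ratio of Myc was 1.34% ± 0.992 against 2.53% ± 1.53 over the 10 other libraries (−0.82, SE 0.61, adjusted p = 0.660) and that of Gata2 1.16% ± 0.425 against 2.09% ± 0.889 (−0.71, SE 0.53, adjusted p = 0.660). Igf2bp2 (−0.84, adjusted p = 0.701), Bmi1 (−1.02, adjusted p = 0.766) and Mecom (0.15, adjusted p = 0.951) were not past the threshold either. Limma called 0 of 13909 genes for LT.HSC against the other types (1371 at an unadjusted p under 0.05) and 0 in the F test among types (1695 at an unadjusted p under 0.05, smallest adjusted p = 0.0537). The F test called 49 genes without GMP 1, 17 without GMP 2 and 1 without LT.HSC 1. The comparison of LT.HSC called 1 higher and 2 lower genes without LT.HSC 1, and 1 lower without GMP 1.

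RNA decay was compared between LT.HSC and MkP after 24 h of labelling. Over the 1247 genes with a ratio at all 7 times in LT.HSC the median ratio was 0.0425% at 0.5 h and 0.0817% at 1 h of chase, and 0.0181%, 0.0162%, 0.0201% and 0.0254% at 6, 9, 12 and 24 h, so it did not fall further after 9 h. In MkP it was 0.109% at 0.5 h and 0.0200%, 0.0145%, 0.0227% and 0.0154% at 6, 9, 12 and 24 h over 1332 genes. Fits through all times include these late values. Among kept fits the median half-life was 3.25 h (95% interval across genes 3.07 to 3.52, 712 genes) in LT.HSC and 4.92 h (4.68 to 5.15, 1680 genes) in MkP. Of 151 genes with a half-life in both, 50 (33.1%, interval 25.7% to 41.2%) were longer lived in LT.HSC, with medians of 3.11 h against 5.71 h. Over every fitted gene the order was the opposite: the median slope was −0.030 per h in LT.HSC and −0.065 per h in MkP, and 62.5% of 5131 genes fell in LT.HSC against 79.0% of 6502 in MkP. Half-lives of the 151 shared genes correlated between LT.HSC and MkP with a Spearman rho of only 0.087. The ranks of single genes by half-life were thus largely unlike between the types. Short-lived transcripts in LT.HSC included the RNA-binding protein gene Larp4 (0.791 h), Ly6c1 (0.797 h) and the mitotic ubiquitin conjugase gene Ube2c (0.850 h), and long-lived ones the pepsinogen gene Pgc (47.1 h), Pdcd1lg2, which encodes a checkpoint ligand (33.5 h), and Fars2 (28.3 h). In MkP the regulator of G-protein signalling gene Rgs18 (0.681 h) was shortest and the kinase C gene Prkca (123 h), Bad (58.8 h) and Arid3a (43.8 h) longest. Half-lives beyond the 24 h of chase are extrapolated from nearly flat lines. The line of Prkca had a slope of −0.0056 per h (SE 0.0027) over 5 times. The short half-lives named here rest on 4 times each. Myc, Igf2bp2 and Mettl3 had no kept fit in LT.HSC. The difference between types depended on the times and genes used. Without 24 h the medians were 2.77 h in both, and 53.5% of 282 shared genes were longer lived in LT.HSC. For genes with a ratio at all 7 times the medians were 6.10 h in LT.HSC and 6.05 h in MkP, and 47.6% of 21 shared genes were longer lived in LT.HSC. The kept fits were 712 in LT.HSC and 1680 in MkP, chosen for falling with R squared of at least 0.5. By the labels, LT.HSC has replicate samples and MkP a single sample per chase time, although the ratios of both were deposited as averages. Noise may differ between the types, and its effect on which fits were kept was not tested. Across 678 genes, which are not independent replicates, half-life and m6A enrichment in LT.HSC correlated with a Spearman rho of 0.039 (interval −0.036 to 0.114).

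**Figure D4:**
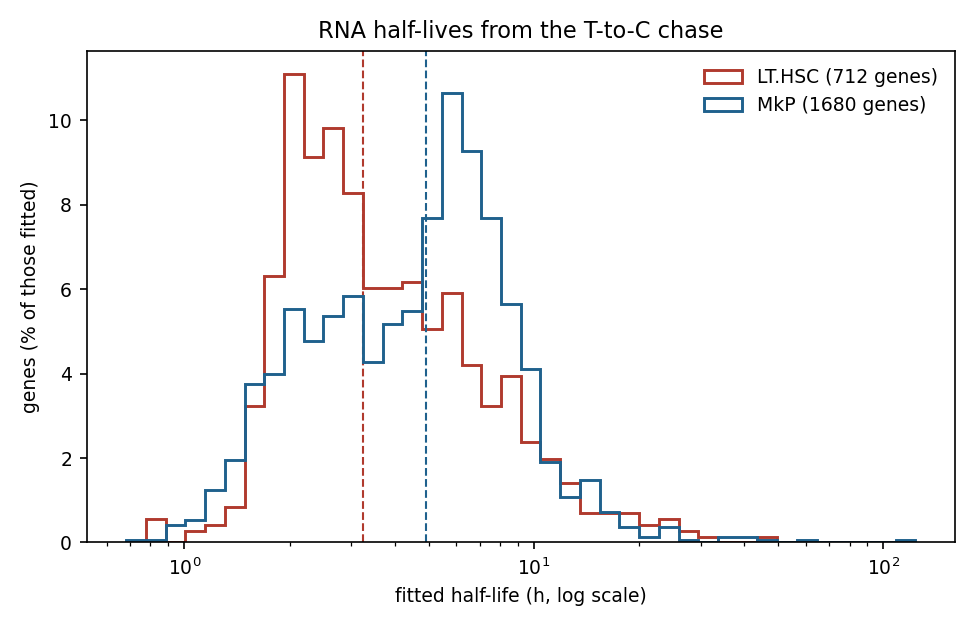
Histogram of RNA half-lives in hours on a log axis, as percent of the genes kept in LT.HSC and in MkP, with dashed lines at the medians of 3.25 h and 4.92 h. The values are from ratios deposited as averages without replicate values. The labels list replicate samples for LT.HSC and a single sample per chase time for MkP.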

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

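The effect of the Mettl3 knockout on P2rx1 and on the gene model A430089I19Rik differed among the 7 cell types by the interaction test. P2rx1 (adjusted p = 0.0157) stood at 133 ± 41.8 (SD, n = 2) in MEP libraries labelled knockout and 1.39 ± 1.96 in wild-type MEP, against 194 and 186 in CMP, 66.5 and 91.1 in GMP, 252 and 206 in LT.HSC, 134 and 147 in MPP, 384 and 469 in MkP and 168 and 253 in ST.HSC. A430089I19Rik (adjusted p = 0.0157) was listed at 0 in wild-type CMP, GMP, MEP and MkP and stood at 110 ± 14.9, 5.87 ± 0.0515, 55.5 ± 12.3 and 113 ± 35.6 in the libraries of those types labelled knockout. In LT.HSC it stood at 0 in the knockout against 0.918 ± 1.30, in MPP at 0.561 ± 0.793 against 0, and in ST.HSC at 0 in both. Causes of these 2 differences were not tested. Without knockout MEP 2 or knockout MkP 1 the interaction test called 0 genes.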

How the results depend on the processing

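With 1 library left out at a time, 1053 refits of counts of genes kept within 1.5 times the full-data count, 85 fell below and 98 rose above. This tally does not measure stability. For a single Mettl3 cell type most refits left out a library of another type, and counts that stayed without a call scored as kept. For Mettl3 expression in LT.HSC, MEP, MPP, MkP and ST.HSC, leaving out any library of the tested type moved the count past this bound. In CMP all but 1 did. For single genes and lists 11786 refits kept the call, 311 lost it and 11 gained it, and under other settings 1703 kept it, 107 lost it, 5 gained it and 1 reversed. A gene past the threshold in neither setting counts as kept even where its sign changed. A group left with 1 library is assumed to vary like the others. The cause was not tested for any change below except where genes or libraries were removed. For IP counts, removing a library also loosened the low-count filter. Settings chosen after seeing the data were recovered reads, leaving out the Erythroid and Monocyte libraries, robust moderation, gene lists in MEP, doubtful libraries, means per genotype and replicate number, genes with a ratio at all 7 times and the set at an unadjusted p.

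Ranges with 1 library left out were 2292 to 4400 higher and 1685 to 3276 lower genes for LT.HSC expression, and 762 to 1523 higher and 221 to 1247 lower for the Mettl3 average. In single types they were 0 to 1 in CMP, 0 to 1611 in LT.HSC, 118 to 367 in MEP, 0 to 6 in MPP, 1 to 351 in MkP, 0 to 1607 in ST.HSC and 0 to 78 for the interaction. For atlas enrichment in LT.HSC they were 117 to 1104 higher and 368 to 2464 lower against 15 types, and 142 to 763 higher and 391 to 1963 lower against MkP. For Mettl3 enrichment they were 0 to 3 higher and 0 to 10 lower on average, 0 to 56 in CMP, 0 to 2612 in GMP, 0 to 201 in LT.HSC, 0 to 1 in MEP, 1 to 620 in MkP and 0 to 783 in ST.HSC. IP counts gave 82 to 270 higher and 34 to 154 lower. New RNA gave 0 to 1 higher, 0 to 2 lower and 0 to 49 among types.

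Without the low-value filter the Mettl3 comparison called 14 genes in CMP, 6 in GMP, 24 in MPP, 33 in ST.HSC, 28 in the interaction and 272 lower on average. Atlas enrichment in LT.HSC had 612 higher genes against the 15 types. Mettl3 enrichment had 11 in CMP, 10 in GMP, 28 in LT.HSC, 17 in MEP, 6 in MPP, 10 in MkP, 21 in ST.HSC, and 1 higher and 2 lower on average. IP counts had 295 higher and 144 lower, the Igf2bp2 comparison 36 and 8, and new RNA 4 higher and 69 among types. In the Mettl3 comparison a pseudocount of 10 gave 221 genes in LT.HSC, 195 in MEP, 6 in MPP, 27 in MkP and 11 in ST.HSC, and 1 in Mettl3 enrichment in MkP. In the atlas it gave 695 and 573 genes more enriched in LT.HSC than in the 15 types and in MkP. For the Mettl3 comparison TMM factors gave 143 in LT.HSC, and edgeR on recovered reads gave 0 in CMP, LT.HSC, MPP and MkP, 165 in MEP and 1 in ST.HSC. Means of 2 against 2 gave 1 higher and 0 lower. DESeq2 size factors gave 1 gene in Mettl3 enrichment in LT.HSC and 131 higher IP genes. Leaving out doubtful libraries gave, in Mettl3 enrichment, 5 genes in LT.HSC, 0 in MEP and 14 in MkP, and beside these 196 higher IP genes and Zfp322a at 0.34. DESeq2 called 689 higher and 203 lower IP genes, and 86 and 66 in the Igf2bp2 comparison. For new RNA among types a pseudocount of 1 gave 12 genes and the arcsine square root 11. With estimated correlation 6 lists stayed called in atlas LT.HSC, 0 in the Mettl3 average and 0 in Igf2bp2. The Igf2bp2 set at an unadjusted p held 283 genes and was not called, with a median of 0.058 (camera p = 0.419, and p = 0.552 with an estimated correlation).

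Median half-lives in LT.HSC and MkP, with the percent of shared genes longer in LT.HSC, were 2.77 h, 2.77 h and 53.5% without 24 h, 2.63 h, 3.51 h and 45.2% at R squared of at least 0.7, and 6.10 h, 6.05 h and 47.6% for genes with a ratio at all 7 times. Without 0.5 h they were 3.62 h, 5.66 h and 27.9%. Libraries with the same replicate number deviated together in part: in the Mettl3 inputs 62 of 91 correlations between groups were over 0.1 (median 0.196, lowest −0.149, 0.294 within a genotype and 0.118 across), so the numbers mark shared structure there without meeting the rule for pairing. Medians were 0.068 in the Mettl3 IP, 0.0066 in the atlas IP and 0.00059 in the atlas inputs, and the single value of the Igf2bp2 set was 0.019. With replicate number as a block, Mettl3 genes called were 225 in LT.HSC, 5 in MPP and 33 in MkP, Mettl3 enrichment in MEP had 0, and the Igf2bp2 comparison had 8 higher genes. The block changed no other count by more than 1.5 times. Depth of 3.42 to 3.55 M in 3 of 4 MEP inputs and 0.819 M in knockout IP MEP 1 limits those comparisons.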

Other observations

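In the atlas, T cell markers peaked in CD4 (8 of 11 genes), B cell markers in B_cell (8 of 9), erythroid markers in Erythroid (11 of 11), megakaryocyte markers in MkP (9 of 12) and granulocyte monocyte progenitor markers in GMP (6 of 7). Dendritic cell markers had their highest mean in DC, where 3 of 10 genes peaked, and lymphoid progenitor markers in B_cell (9.67, with 3 of 8 genes peaking there) ahead of CLP (9.55). All 9 neutrophil markers peaked in the libraries labelled Monocyte, with a mean log2 value of 20.7 against 17.4 in those labelled Neutrophil. Monocyte markers also peaked in Monocyte, with 4 of 8 genes and a mean of 13.2 against 12.3 in Neutrophil. The size factors put a read at 7.97 and 11.6 units in the Monocyte libraries, against 1.25 and 1.45 in Neutrophil. The deposited values summed to 83132278 and 113240258 in Monocyte and to 20073902 and 21090990 in Neutrophil. Relative to these totals the mean of neutrophil markers stayed higher in Monocyte, while that of monocyte markers was lower there. The sizes of both differences, and the direction for monocyte markers, therefore depend on the normalisation.

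MkP libraries of the atlas carried granule transcripts, with Mpo at 573180 and 442750 and Elane at 135930 and 205550, beside the platelet chemokine gene Pf4 at 16351 and 76286. In the Mettl3 set, normalised separately, Pf4 in MkP stood at 3137 and 909 in the libraries labelled knockout and at 35563 and 25623 in the wild type, and Gp1bb at 413 and 103 against 5975 and 3813. The integrin gene Itga2b stood at 7721 and 6008 against 9030 and 5623. The knockout MkP libraries were unlike each other in granule RNA. Mpo stood at 1407 and 37011 against 32197 and 27726 in the wild type, and Elane at 230 and 4017 against 10213 and 10561. The genes named for MkP here were chosen after their values were seen.

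The first pattern weighed is the Mettl3 average in expression, with 1522 genes called; the list of mast cell and basophil genes was written after the result was seen. Of 100 splits of the libraries into sides of equal make-up, 1, the real split, called at least as many genes, and the highest other called 56. These splits exchanged labels within each cell type and so broke up the sets of libraries that deviate together. They therefore cannot test a random division of whole sets. Splitting the 4 sets of 7 libraries by replicate number called 651 genes and the remaining split 1. Structure shared by the libraries of a set could thus account for part or all of the calls. The prediction that both other splits would stay under 0.5 of the real count if the sets had no such structure was met, but with 4 sets there are only 3 splits, and 651 calls without a genotype difference show structure, so that prediction was wrong for this design. Of 10 mast cell and basophil genes 4 passed as higher, with a median of 1.16, which leaves a difference in cell make-up possible beside an effect of METTL3 loss. For the other tests of this set, 1 of 25 splits of the IP counts reached the real 104 genes (highest other 3). Those splits broke up the sets in the same way. For enrichment the real count was 0, which any split reaches, so its 100 of 100 splits (highest other 0) carry no information.

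The second pattern is the m6A enrichment of LT.HSC against MkP, with 1420 genes called. In the other wild-type libraries 53.2% of the genes called had the same sign, and the correlation across genes was 0.047 (48.2% and 0.018 without doubtful libraries). The share was 64.8% for genes more enriched in LT.HSC and 50.7% for those less enriched, where 45.3% of all genes were lower. Without doubtful libraries these values were 55.65%, 46.6% and 44.2%. Noise of single libraries could thus be a source of many calls. The MkP libraries of the 2 sets were unlike in granule RNA, with Mpo at 51740 and 29972 CPM in the atlas and 3933 and 3532 in the Mettl3 wild type, and such a difference between populations could lower the agreement too. Expression between the same types, by comparison, kept its sign in 71.4% of 7690 genes. The input difference was larger than the IP difference in 45.6% of the genes called and in 45.9% of all 16639 genes tested. The spread of the first value, from 33.8% to 56.1% with 1 of the 8 libraries left out, was added after the value was seen. The bound of 50% set for this test was wrong for its design, because genes called on IP minus input carry noise of both parts, so inputs as the source stay open. A difference in m6A itself between LT.HSC and MkP was not separated from these by a test.

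The third pattern is Bmi1 in the Igf2bp2 set, with 1 count in each library labelled knockout; the depth test was written after the result was seen. At the lower wild-type share the shallower knockout library would hold 55.0 counts of Bmi1, which argues against sequencing depth. Random loss of transcripts could still be the source, since 2 genes, Bmi1 and Armcx6, were lost in both libraries of 1 side in the real split and up to 4 genes in another split of the 4 libraries. An effect of IGF2BP2 loss on Bmi1 could not be told from this with 2 libraries per genotype.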
